A study of Ovis aries with 30 samples.

How the data were processed

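Total RNA was extracted with Trizol from frozen sheep lung and kidney, and biotin-labelled RNA was hybridised to an Affymetrix bovine array, per the labels' protocols. The 30 arrays form 6 groups of 5 by tissue and age, taken from the sample titles. The submitters' design text speaks of biological replications, and no batch, date or scanner file was used here. The deposited table holds log2 expression of 24128 probe sets in 30 arrays, and per the submitters' processing notes RMA and Partek were used, with versions not given in the sources used here. RMA corrects background, normalises arrays to a common distribution and combines the probes of a set, which makes log2 values comparable between arrays and compresses changes of dim probe sets. The array carries bovine probes, so a sheep transcript that differs in sequence can read low whatever its level. No table column was left unmapped to a sample (0 columns). Detection calls were not used here, so no gene was called absent, and signal over background is unknown.

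Probe sets were named from the platform annotation supplied with the values: 13318 had 1 symbol, 86 had several and 10724 were not listed with a gene. Of the gene symbols tested, 8492 were also in a sheep gene table, which gave no Entrez identifier match (0), so no genome position is given. Probe sets with several symbols or none and the 112 control probe sets stayed out of gene tests. Each of the 9155 genes was represented by its probe set with the highest mean over all 30 arrays. For 2913 genes with more than 1 probe set this choice could change the result.

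Comparisons were fitted with limma 3.58.1 in R 4.3.3, by lmFit and eBayes, on the deposited log2 values. Age comparisons used the 15 arrays of a tissue, which share one estimate of the spread, and tissue comparisons and tissue-by-age interactions used all 30 arrays. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison, with a threshold of 0.05. Across 35 gene lists written before the data were examined, 34 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists of a comparison, and again with a correlation estimated from the data. Fewer than 5 members were measured for the sex-linked transcripts. Calls of list members are given over all genes and adjusted over the list alone. Some list symbols were updated to the annotation's current ones after it was seen. Overlaps between tissues were set against the product of both lists' sizes divided by the genes tested. The share of the fetal-to-adult fall present at 10 weeks was the fetal-to-10-week difference of the group means over the fetal-to-adult difference, with a 95% interval from 10000 bootstrap draws of arrays within groups.

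Genes named in the text follow a rule set before the data were examined: the 6 largest rises and 6 largest falls of each age comparison among called genes whose arrays did not overlap between ages, up to 4 called members of each list by smallest adjusted p, the 4 largest differences per direction of each tissue comparison and interaction, the 8 genes per direction with the largest smaller change in both tissues, and a fixed set of growth genes. Of that set IGF2, MEST, PEG3, PLAGL1, DLK1, IGF2BP1, IGF2BP3, CDK1 and EZH2 were measured. Symbols that are only locus or clone identifiers were passed over. Genes outside this rule are said to have been chosen after their values were seen. XIST, and the genes used to describe the fetal lung arrays, are of that kind.

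The fit was tested on simulated arrays of the same 9155 genes with known changes of 0.5, 1 and 2 log2. These were given to 67, 67 and 66 genes. Noise was independent between genes, with 1 spread per gene for all groups and no outlying array. Recovery and false calls in the real arrays may therefore differ from those below. For kidney from 10 weeks to adult it recovered 64.2%, 98.5% and 98.5% of changed genes, with 11 false among 185 calls, and for lung at that interval 58.2%, 82.1% and 95.5%, with 6 false among 163 calls. For the interaction from fetal day 90 to adult it recovered 26.9%, 64.2% and 95.5%, with 3 false among 127 calls.

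Alternatives set before the data were examined were leaving out the 25% of genes with the lowest mean, the mean of all probe sets of a gene, leaving out the multi-transcript probe sets (those whose names mark several transcripts of one gene, transcripts of different genes or probes similar to other sequences), repeated quantile normalisation, centring arrays on their medians, eBayes with trend and robust settings, array quality weights, other sets of arrays in the fit, a 2-fold threshold added to the test, the replicate number as a block, an estimated correlation for the lists and leaving out each array in turn. Leaving out fetal lung arrays 26B and 80B was chosen after the data were seen, as were a list of 12 liver proteins first seen in those arrays and a list of further hepatocyte genes, of which 32 were measured. Other splits of the arrays, 100 per comparison with the real one included, were drawn for each count.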

Results

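Gene expression was measured in lung and kidney of sheep (Ovis aries) at 3 ages: fetal day 90, 10 weeks after birth and adulthood. Each tissue and age was represented by 5 arrays, 30 in all. Each array was an Affymetrix bovine expression array hybridised with biotin-labelled RNA from frozen tissue. The title of the series concerns a growth-regulating genetic program and its pace. The comparisons addressed here were the change with age within each tissue, the genes that changed the same way in both tissues, the genes whose change differed between tissues, and how much of the fetal-to-adult fall was present at 10 weeks. Values were log2 expression of 24128 probe sets, from 2.44 to 15.23, and 9155 genes were tested. Array medians lay between 6.57 and 6.81. The correlation of 2 arrays of one group across genes was 0.980 or higher in every group except the lung at 10 weeks (lowest 0.973) and the fetal lung (lowest 0.906). The first principal component held 52.8% of the variance between arrays and the second held 21.6%. XIST, the transcript of the inactive X chromosome, had group means between 11.5 and 11.9 in all 6 groups. Changes below are log2 values with their standard errors, from limma with 5 arrays per group. Set test p-values are at the preset correlation unless stated, and are too small where genes of a list vary together more than that. In lung from fetal day 90 to 10 weeks it called 21 of 34 lists, and an estimated correlation called 11. There, 14 of 100 splits of the arrays, the real one included, called as many as 21.

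The fetal lung arrays were not alike. Over 12 transcripts of liver proteins, arrays 26B and 80B had means of 12.6 and 11.6, whereas arrays 10A, 14A and 14B had 7.67, 6.81 and 6.43. The arginase gene ARG1, an enzyme of the urea cycle, stood at 12.87 and 11.98 in these 2 arrays and between 5.92 and 6.75 in the other 3. Surfactant protein C (SFTPC), a product of alveolar type II cells, read 9.30 in array 26B and 10.98 in array 80B against 11.4 to 11.6 in the other 3. Values from arrays 10A, 14A and 14B alone, an alternative chosen after the data were seen, stand beside some of the results that use the fetal lung. Arrays 14A and 14B share the number in their titles. Whether they come from related animals is not stated there, and each was taken as a separate replicate. Both are in the alternative of 10A, 14A and 14B alone. If they are related, its spread and adjusted p-values may be too small.

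**Figure D1:**
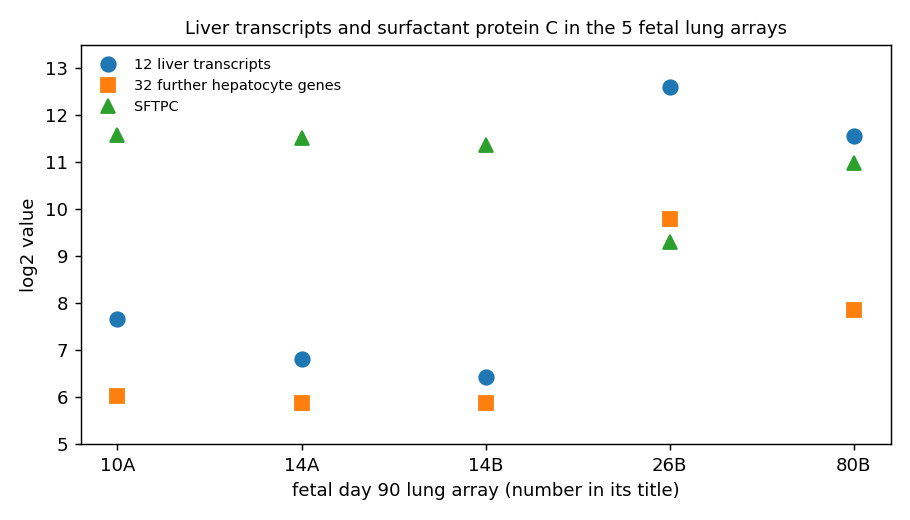
Log2 values in the 5 fetal day 90 lung arrays (horizontal axis, by their number). Circles are the mean of 12 liver transcripts, squares the mean of 32 further hepatocyte genes and triangles SFTPC. The circles of 26B (12.6) and 80B (11.6) lie above the highest of the other 3 arrays (7.67).

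In kidney, the growth-related genes of the fetus fell between fetal day 90 and 10 weeks while genes of the mature tubule rose. IGF2, the fetal insulin-like growth factor, fell by 2.29 ± 0.29 (adjusted p = 6.45e-06). MEST, an imprinted gene of growing tissue, fell by 4.0 ± 0.18 (adjusted p = 2.33e-11) and IGF2BP3, a fetal RNA-binding protein, fell by 2.60 ± 0.21 (adjusted p = 3.37e-08). A MEST probe set nearly as bright as the one used fell less, reading 9.90 in fetal kidney, 8.80 at 10 weeks and 8.91 in adults. PEG3 fell by 2.18 ± 0.20, PLAGL1 fell by 1.35 ± 0.10, IGF2BP1 fell by 1.51 ± 0.12 and DLK1, a Notch-related protein of growing tissue, fell by 0.80 ± 0.14. A dimmer DLK1 probe set fell more, from 12.20 to 10.08. Of the list of imprinted growth genes, 15 of 17 measured members fell and 0 rose (16 fell and 1 rose when adjusted over the list alone), with a set test adjusted p of 6.2e-09. Its smallest p-values after MEST belonged to NNAT, which fell by 3.15, CDKN1C, which fell by 1.63, and PHLDA2, which fell by 3.18. Of the fetal growth regulators 9 of 11 fell (9 adjusted over the list alone; set test adjusted p = 1.0e-06), among them the heparin-binding growth factor MDK, which fell by 3.98 ± 0.11, and the histone methyltransferase EZH2, which fell by 1.67 ± 0.11. The call for IGF2 depended on its probe set. The brightest of 4 averaged 11.6 in fetal kidney and 9.33 at 10 weeks, and a dimmer set 7.71 and 6.79. The other 2 read 6.84 and 7.16, and 4.77 and 5.0. The name of the brightest marks probes shared by several transcripts of one gene. Leaving out multi-transcript probe sets, those named as matching several transcripts of one gene or of different genes, the IGF2 change was 0.32. Here and below, that IGF2 value came from the brightest remaining set, which read 6.84 and 7.16 in kidney. The set at 7.71 and 6.79, which fell, also remained.

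Cell division genes fell with them. Of 32 mitotic cell cycle genes measured, 30 fell (30 adjusted over the list alone; set test adjusted p = 1.0e-15), for example the mitotic kinase CDK1, which fell by 2.34 ± 0.19, the kinetochore gene NDC80, which fell by 3.01 ± 0.21, and the replication helicase genes MCM6 and MCM4, which fell by 1.64 and 1.60. The chromatin and DNA methylation list fell in 9 of 16 members (9 adjusted over the list alone; set test adjusted p = 6.9e-05), with DNMT3A, a DNA methyltransferase, which fell by 1.43 ± 0.10, and UHRF1, which partners DNMT1 and fell by 2.71 ± 0.29. Genes of fibrillar collagen and elastic fibre fell in 20 of 25 members and rose in 1 (21 and 1 adjusted over the list alone; set test adjusted p = 5.7e-10): periostin (POSTN) fell by 3.76 ± 0.13, fibronectin (FN1) fell by 2.98 ± 0.14 and versican (VCAN) fell by 3.98 ± 0.26. Nephron progenitor and kidney development genes fell in 6 of 11 and rose in 2 (the same adjusted over the list alone), including BMP7, which fell by 2.80, and the ureteric bud receptor RET, which fell by 1.62. That list's set test gave adjusted p = 0.017, and adjusted p = 0.10 with an estimated correlation.

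Proximal tubule genes rose in 17 of 20 members and fell in 1 (the same counts adjusted over the list alone; set test adjusted p = 2.1e-09). The organic anion transporters SLC22A6 and SLC22A8, which secrete drugs and metabolites into the urine, rose by 6.74 ± 0.23 (adjusted p = 9.26e-13) and 5.80 ± 0.25 (adjusted p = 1.76e-11), the gluconeogenic enzyme PCK1 rose by 3.31 ± 0.14 and the water channel AQP1 rose by 2.16 ± 0.13. SLC22A6 went from 4.94 ± 0.25 (SD, n = 5) in fetal kidney to 11.7 ± 0.27 at 10 weeks. Distal nephron genes rose in 8 of 16 (8 adjusted over the list alone; set test adjusted p = 0.0014), with uromodulin (UMOD) rising by 1.43 ± 0.12 and the thiazide-sensitive cotransporter SLC12A3 by 1.90 ± 0.18. Fatty acid oxidation genes rose in 20 of 22 (21 adjusted over the list alone; set test adjusted p = 4.1e-10) and genes of xenobiotic and antioxidant enzymes in 24 of 30, with 1 lower (the same adjusted over the list alone; set test adjusted p = 5.5e-08), such as ACAA1, which rose by 1.93, and AOX1, which rose by 4.72 ± 0.22. Of 41 oxidative phosphorylation genes 15 rose and 0 fell (15 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.44 with an estimated correlation). MHC class II presentation genes rose in 8 of 13 (8 adjusted over the list alone; set test adjusted p = 0.0031) and interferon response genes in 10 of 19 (11 adjusted over the list alone; set test adjusted p = 0.010), for instance BOLA-DRA by 1.85 and RSAD2 by 1.03. Macrophage and monocyte genes rose in 11 of 19 and fell in 2 (the same adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.29 with an estimated correlation). In all, 4111 of 9155 genes differed between the 2 ages in kidney, 2188 higher and 1923 lower at 10 weeks. The largest rises also included HRG (5.62), ACSM1 (5.05) and PON3 (4.53). The largest falls were those of HBB (fell by 8.03 ± 0.08), CRABP1 (fell by 5.84), HBG (fell by 5.61), NPVF (fell by 5.25), alpha-fetoprotein AFP (fell by 5.0) and CUX2 (fell by 4.93). The HBB change was -0.76 and the AFP change -0.38 without multi-transcript probe sets. HBB and HBG are globin genes of high sequence similarity, and their probe sets on this bovine array may not tell the sheep globins apart.

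**Figure D2:**
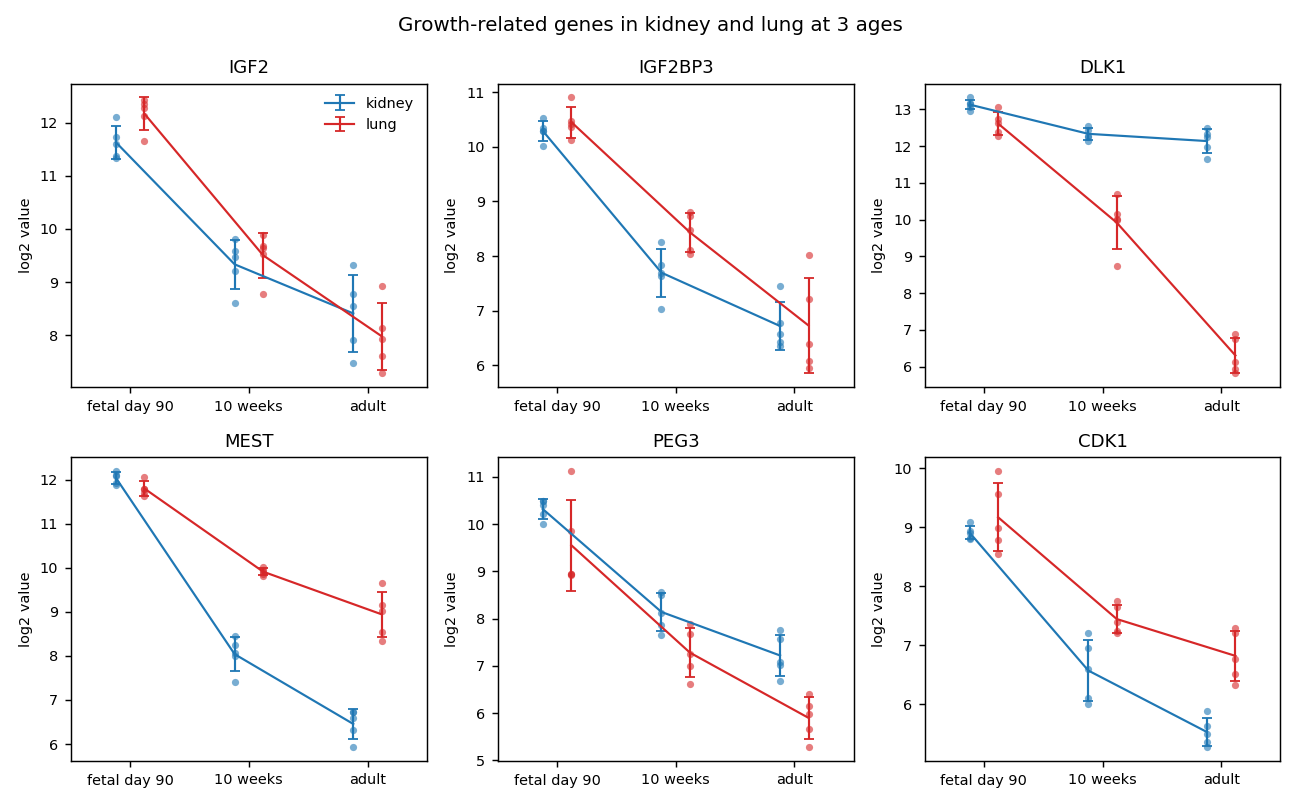
Log2 value (vertical axis) of 6 growth-related genes at the 3 ages (horizontal axis), kidney in blue and lung in red. Points are arrays and lines join the means of 5 arrays with their SD. IGF2 means went from 11.6 to 9.33 to 8.41 in kidney and from 12.2 to 9.50 to 7.98 in lung, and DLK1 means from 13.1 to 12.3 to 12.1 in kidney and from 12.6 to 9.92 to 6.30 in lung.

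From 10 weeks to adulthood the kidney changed far less. Among the 164 genes that fell were again genes of cell division, matrix and growth: cyclin B1 (CCNB1) fell by 1.65 ± 0.23 (adjusted p = 7.63e-04), the chromosomal passenger gene CDCA8 fell by 1.64 ± 0.20 (adjusted p = 1.97e-04), MEST fell by 1.58 ± 0.18 (adjusted p = 1.13e-04) and the type III and type V collagen genes COL3A1 and COL5A2 each fell by 1.21 ± 0.11 (adjusted p = 2.11e-05). Mitotic genes fell in 12 of 32 (18 adjusted over the list alone; set test adjusted p = 2.4e-15) and fibrillar collagen and elastic fibre genes fell in 9 of 25 and rose in 1 (11 and 1 adjusted over the list alone; set test adjusted p = 4.6e-08), among them elastin (ELN), which fell by 0.85, and SPARC, which fell by 0.88. Imprinted growth genes fell in 4 of 17 (7 adjusted over the list alone), namely MEST, NNAT, PEG3 and IGF2R, with set test adjusted p = 3.1e-05 and adjusted p = 0.056 with an estimated correlation. Fetal growth regulators fell in 4 of 11 (5 adjusted over the list alone), namely GPC3, PTN, IGF2BP3 and EZH2, with set test adjusted p = 0.00016 and adjusted p = 0.062 with an estimated correlation. CDK1 fell by 1.04 ± 0.19. The MEST fall is that of its brightest probe set, which read 8.04 at 10 weeks and 6.46 in adults. A MEST set nearly as bright did not fall (8.80 and 8.91), and the dimmer ones read 5.19 and 4.61, and 4.74 and 4.79. The IGF2 change of -0.92 ± 0.29 did not pass the threshold (adjusted p = 0.106), nor did those of DLK1 (-0.20, adjusted p = 0.562), PLAGL1 (-0.18, adjusted p = 0.457) and IGF2BP1 (-0.08, adjusted p = 0.835).

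The largest rises from 10 weeks to adult kidney were MYBPC1 (3.08 ± 0.37), the potassium channel subunit KCNE1 (2.31 ± 0.22), the alcohol dehydrogenase ADH4 (1.89 ± 0.35), SERPINI1 (1.69), S100B (1.49) and STMN2 (1.42). CIT, CNMD and ACSM2B fell by 1.59, 1.58 and 1.57. Of the proximal tubule list 1 of 20 rose, the aminopeptidase ANPEP (0.73), and 0 fell (set test adjusted p = 0.79). The distal list had 1 member higher, the sodium channel subunit SCNN1A (0.58), and 1 lower, the water channel AQP3, which fell by 1.06. The plasma cell genes JCHAIN and IGHM rose by 0.89 and 1.25. Macrophage and monocyte genes fell in 2 of 19 (5 adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.26 with an estimated correlation), CSF1R and FCER1G, which fell by 0.53 and 0.47. Interferon response genes fell in 1 of 19 (2 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.056 with an estimated correlation), ISG15, which fell by 0.72. In all 300 of 9155 genes differed, 136 higher and 164 lower in the adult. That count was 137 with all 30 arrays in the fit and 158 with only the 10 arrays compared.

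Between fetal day 90 and adulthood kidney differed in 4198 genes, 2179 higher and 2019 lower in the adult. MEST fell by 5.58 ± 0.18 (adjusted p = 3.76e-13), IGF2BP3 fell by 3.57 ± 0.21, IGF2 fell by 3.22 ± 0.29, PEG3 fell by 3.10 ± 0.20. EZH2 fell by 2.12 ± 0.11, IGF2BP1 fell by 1.59 ± 0.12, PLAGL1 fell by 1.53 ± 0.10 and DLK1 fell by 0.99 ± 0.14. Imprinted growth genes fell in 16 of 17 members (set test adjusted p = 2.4e-10), fetal growth regulators in 10 of 11 (set test adjusted p = 2.8e-08) and mitotic genes in 30 of 32 (set test adjusted p = 4.0e-19), the same numbers as adjusted over the list alone. CDK1 fell by 3.38, UBE2C by 3.92 and NDC80 by 4.22. Without multi-transcript probe sets the IGF2 change was 0.29. Fibrillar collagen and elastic fibre genes fell in 21 of 25 (23 adjusted over the list alone; set test adjusted p = 7.2e-13), with COL1A1 falling by 2.93 ± 0.17. Proximal tubule genes rose in 18 of 20 (18 adjusted over the list alone; set test adjusted p = 7.5e-10) and fatty acid oxidation genes in 20 of 22 (20 adjusted over the list alone; set test adjusted p = 4.7e-10), including the lipid-sensing receptor PPARA, which rose by 1.82 ± 0.11. Largest among the rises were HRG (6.51), SLC22A6 (6.28), AKR1C3 (5.74), SLC22A8 (5.66), FGL2 (5.46) and AOX1 (4.80), and among the falls HBB (fell by 8.04, or -1.03 without multi-transcript probe sets), AFP (fell by 6.67, or -0.34 without them), HBG (fell by 5.97), CRABP1 (fell by 5.94) and NPVF (fell by 4.90).

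In lung, the same growth genes fell between fetal day 90 and 10 weeks, and genes of alveolar cells, airway and immune cells rose. IGF2BP1 fell by 3.15 ± 0.18 (adjusted p = 6.87e-09), DLK1 fell by 2.70 ± 0.31 (adjusted p = 8.58e-06), IGF2 fell by 2.66 ± 0.27 (adjusted p = 2.86e-06). PEG3 fell by 2.27 ± 0.39 (adjusted p = 4.0e-04), IGF2BP3 fell by 2.02 ± 0.33 and MEST fell by 1.89 ± 0.19. The MEST probe set nearly as bright as the one used read 9.87 in fetal lung and 9.54 at 10 weeks. PLAGL1 fell by 0.84 ± 0.18 and EZH2 by 1.32 ± 0.22. Imprinted growth genes fell in 12 of 17 and rose in 1 (13 and 1 adjusted over the list alone; set test adjusted p = 1.7e-06), among them the noncoding RNA MEG3, which fell by 2.37, and PEG10, which fell by 1.63. Fetal growth regulators fell in 9 of 11 (9 adjusted over the list alone; set test adjusted p = 1.5e-05, and with arrays 10A, 14A and 14B alone adjusted p = 0.073 with an estimated correlation), MDK falling by 3.07 ± 0.35. Mitotic genes fell in 28 of 32 (29 adjusted over the list alone; set test adjusted p = 1.2e-13), but that list's adjusted p was 0.13 with an estimated correlation. CDK1 fell by 1.72 ± 0.25 and the mitotic kinesin KIF20A by 2.21 ± 0.21. Without multi-transcript probe sets the IGF2 change was 0.22. Chromatin and DNA methylation genes fell in 10 of 16 (12 adjusted over the list alone; set test adjusted p = 1.0e-05), UHRF1 falling by 2.0 and DNMT3A by 1.21. Fibrillar collagen and elastic fibre genes moved both ways at this interval: 5 of 25 fell and 4 rose, and the set test gave adjusted p = 0.97. Their mean was 10.24 in fetal lung and 10.24 at 10 weeks, but 9.42 in array 26B. In arrays 10A, 14A and 14B alone it was 10.47, with 9 members falling and 3 rising at 10 weeks (adjusted p = 0.19).

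Surfactant and alveolar genes were higher at 10 weeks. Alveolar type II and surfactant genes rose in 8 of 16 (8 adjusted over the list alone; set test adjusted p = 0.00028), and in 8 with arrays 10A, 14A and 14B alone, led by surfactant protein D (SFTPD, 3.46 ± 0.16, adjusted p = 7.81e-10), SFTPA1 (1.67 ± 0.15) and SFTPB (2.01 ± 0.32). That list averaged 7.39 in array 26B and 7.90 in the other 4 fetal arrays. Alveolar type I and lung capillary genes rose in 12 of 14 (12 adjusted over the list alone; set test adjusted p = 1.3e-07), with the water channels AQP1 and AQP5 rising by 2.46 ± 0.17 and 1.74 ± 0.13. Airway epithelium genes rose in 7 of 12 (7 adjusted over the list alone; adjusted p = 6.1e-05, and adjusted p = 0.095 with an estimated correlation), among them PIGR, the receptor that carries immunoglobulin across epithelium, by 4.08 ± 0.20. Endothelial genes rose in 12 of 19 (13 adjusted over the list alone; adjusted p = 7.8e-05, and adjusted p = 0.17 with an estimated correlation), TEK by 0.77. Their mean was 8.36 in array 26B and 8.98 in the other 4, and 12 also rose with arrays 10A, 14A and 14B alone.

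Genes of several immune cell types rose in the same interval, while of the granulocyte and mast cell genes 3 of 15 rose and 4 fell (the same adjusted over the list alone; set test adjusted p = 0.97). Macrophage and monocyte genes rose in 18 of 19 (18 adjusted over the list alone; set test adjusted p = 4.5e-13), with FABP4, a lipid-binding protein of alveolar macrophages and fat cells, rising by 3.93 ± 0.29 and the receptor CSF1R by 2.17 ± 0.19. That list averaged 7.86 in array 26B and 6.92 in the other 4 fetal arrays, and 18 rose with arrays 10A, 14A and 14B alone as well. T and NK cell genes rose in 13 of 19 (14 adjusted over the list alone; set test adjusted p = 1.3e-08), CD3E by 2.93 ± 0.18, and B and plasma cell genes in 8 of 11 (9 adjusted over the list alone; set test adjusted p = 1.9e-07), IGHM by 4.87 ± 0.18. MHC class II presentation genes rose in 8 of 13 (8 adjusted over the list alone; set test adjusted p = 1.4e-06) and interferon response genes in 13 of 19 (14 adjusted over the list alone; set test adjusted p = 1.7e-06, and with arrays 10A, 14A and 14B alone adjusted p = 0.073 with an estimated correlation). Immediate early and heat shock genes, which respond within minutes to injury and handling of tissue, rose in 13 of 21 and fell in 2 (13 and 3 adjusted over the list alone; adjusted p = 2.4e-05, and adjusted p = 0.14 with an estimated correlation), ZFP36 by 3.51 ± 0.22 and NR4A1 by 2.54 ± 0.23. The actin 3' minus 5' difference of the arrays, a sign of RNA quality, lay higher at later ages in lung, between 0.89 and 1.83 in the fetus, 1.84 and 2.63 at 10 weeks and 2.52 and 4.54 in adults. In kidney it lay between 1.22 and 1.60 in the fetus, 0.49 and 1.18 at 10 weeks and 0.59 and 1.33 in adults. For the GAPD control the 3' minus 5' difference overlapped between the ages of lung. It lay between -0.64 and -0.07 in the fetus, -0.71 and 0.61 at 10 weeks and -0.12 and 0.21 in adults. In all 2820 genes differed, 1421 higher and 1399 lower at 10 weeks, and with fetal arrays 10A, 14A and 14B alone 3439, of which 2552 were shared. With array quality weights 4824 were called. The largest rises were CCL3 (5.61), SAA3 (5.18), SPINK1 (5.10), UCP3 (4.91), IGHM and LPO (4.87). UCP3, an uncoupling protein best known from muscle, went from 4.49 ± 0.07 (SD, n = 5) to 9.40 ± 0.55.

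The largest lung falls at 10 weeks were HBB (fell by 6.36 ± 0.56), AFP (fell by 5.61 ± 1.02), the cartilage collagen COL2A1 (fell by 4.78 ± 0.49), ARG1 (fell by 4.63 ± 1.14), CPS1 (fell by 4.61 ± 0.92) and APOH (fell by 4.59 ± 1.04). AFP, ARG1, CPS1 and APOH are transcripts of fetal or adult liver, high in arrays 26B and 80B. With arrays 10A, 14A and 14B alone AFP fell by 3.57, ARG1 fell by 2.15, CPS1 fell by 2.63 and APOH fell by 2.62, and COL2A1 fell by 5.38. Over the 12 liver transcripts these arrays still had means of 6.43 to 7.67, against 4.74 to 5.32 in lung at 10 weeks. Their falls in liver transcripts may thus carry some liver signal too, which was not tested. Without multi-transcript probe sets, but with all 5 arrays, the HBB change was -1.58 and the AFP change -0.30 (adjusted p = 0.407). The erythroid list fell in 4 of 17 members in all 5 arrays (4 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.49 with an estimated correlation). Its mean was 8.89 in array 26B and 7.67 in array 80B against 6.66 to 6.81 in the other 3, and with those 3 alone the set test gave adjusted p = 0.30.

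**Figure D3:**
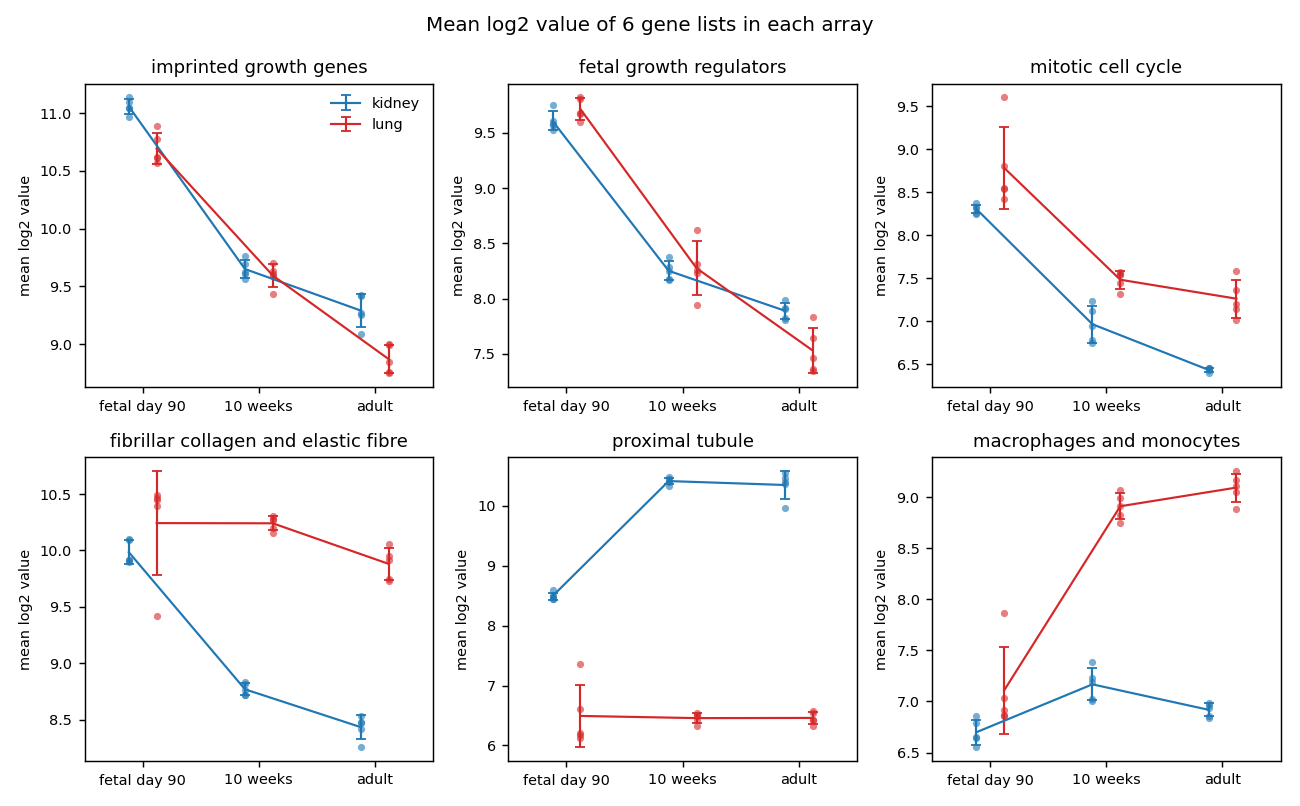
Mean log2 value of 6 gene lists in each array (vertical axis) at the 3 ages (horizontal axis), kidney in blue and lung in red. Points are arrays and lines join the means of 5 arrays with their SD. The imprinted growth gene means were 11.1, 9.65 and 9.29 in kidney and 10.7, 9.59 and 8.87 in lung.

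From 10 weeks to adult lung, some of the imprinted genes and other growth genes fell further. DLK1 fell by 3.61 ± 0.31 (adjusted p = 2.58e-05), IGF2BP3 fell by 1.71 ± 0.33 (adjusted p = 0.0104), IGF2 fell by 1.52 ± 0.27 (adjusted p = 0.00675) and MEST fell by 0.97 ± 0.19 (adjusted p = 0.0113). The IGF2 change was -0.23 (adjusted p = 0.392) without multi-transcript probe sets. A MEST probe set nearly as bright as the one used read 9.54 at 10 weeks and 9.44 in adults. IGF2BP1 (0.01, adjusted p = 0.989) and EZH2 (-0.34, adjusted p = 0.475) did not pass. Imprinted growth genes fell in 6 of 17 and 0 rose (10 fell when adjusted over the list alone; set test adjusted p = 1.9e-12), including PEG10, which fell by 1.36 ± 0.15, MAGEL2, which fell by 0.81, and CDKN1C, a cell cycle inhibitor, which fell by 0.54. Of the fetal growth regulators DLK1 and IGF2BP3 fell (2 of 11, 4 adjusted over the list alone), with adjusted p = 2.5e-05 and adjusted p = 0.11 with an estimated correlation. PEG3 (-1.38 ± 0.39, adjusted p = 0.0665) and PLAGL1 (-0.67 ± 0.18, adjusted p = 0.0592) did not pass with all fetal arrays in the fit but did without arrays 26B and 80B, which set the spread only (adjusted p = 0.00258 and 0.0219). Of 32 mitotic genes 0 were called, 0 when adjusted over the list alone. As a set they were lower (median -0.20, adjusted p = 0.0014, and adjusted p = 0.89 with an estimated correlation), CDK1 being at -0.62 ± 0.25 (adjusted p = 0.203). Fibrillar collagen and elastic fibre genes fell in 5 of 25 (8 fell and 1 rose adjusted over the list alone; adjusted p = 3.1e-07, and adjusted p = 0.56 with an estimated correlation), ELN by 1.58 ± 0.28 and COL1A1 by 1.04 ± 0.20.

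The largest lung rises after 10 weeks were those of the class II genes BOLA-DQB1 (5.47 ± 0.51) and BOLA-DQA1 (4.91 ± 0.61), the matrix protease ADAMTS4 (2.68), CCN5 (2.61), FOLR3 (2.47) and the chemokine CCL26 (2.34 ± 0.15, adjusted p = 1.60e-06). DQ genes are polymorphic and duplicated in ruminants, so their probe sets are uncertain. BOLA-DQB1 was also low at 10 weeks, at 5.75 to 6.38 against 7.30 to 9.88 in fetal lung. BOLA-DQB1 changed by 0.30 (adjusted p = 0.264) and FOLR3 by 0.08 (adjusted p = 0.927) without multi-transcript probe sets. HBB rose by 3.04 ± 0.56 with its brightest probe set, with adult arrays between 8.38 and 12.3, and the change was -0.26 without multi-transcript probe sets. GFRA2, NUDT11, DNAJC12 and VEGFD fell by 2.33, 2.09, 1.84 and 1.72. SFTPA1 rose by 0.95 ± 0.15 and SFTPD by 0.69 ± 0.16, 2 of the 16 alveolar type II and surfactant genes (3 adjusted over the list alone; set test adjusted p = 0.14). Immediate early and heat shock genes rose in 6 of 21 (12 adjusted over the list alone; adjusted p = 2.7e-08, and adjusted p = 0.19 with an estimated correlation), ATF3 by 2.21 ± 0.31, while the actin 3' minus 5' difference lay between 1.84 and 2.63 at 10 weeks and 2.52 and 4.54 in the adult arrays. In all 289 genes differed, 195 higher and 94 lower. The count depended on which arrays set the spread. It was 1020 without fetal arrays 26B and 80B, with the 289 among them, 689 with only the 10 compared and 751 with all 30. With array quality weights, which also weight the arrays compared, it was 1204. It was 165 without adult array AD-286, 165 without 10-week array 7 and 183 without adult array AD-204.

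Between fetal day 90 and adulthood lung differed in 3444 genes, 1889 higher and 1555 lower in the adult (3839 with arrays 10A, 14A and 14B alone, 3079 of them shared). DLK1 fell by 6.31 ± 0.31 (adjusted p = 7.91e-10), IGF2 fell by 4.19 ± 0.27 (adjusted p = 1.58e-08), IGF2BP3 fell by 3.73 ± 0.33, PEG3 fell by 3.66 ± 0.39, IGF2BP1 fell by 3.14 ± 0.18. MEST fell by 2.85 ± 0.19, CDK1 fell by 2.35 ± 0.25, EZH2 fell by 1.66 ± 0.22 and PLAGL1 fell by 1.51 ± 0.18. A MEST probe set nearly as bright as the one used fell less, reading 9.87 in fetal and 9.44 in adult lung. The IGF2 value is that of its brightest probe set, 12.2 in fetal and 7.98 in adult lung. A dimmer set read 8.14 and 6.46, and the other 2 read 7.15 and 7.14, and 5.19 and 5.04. Without multi-transcript probe sets the change was -0.01 (adjusted p = 0.945), from the set at 7.15 and 7.14. The set at 8.14 and 6.46, which fell, is not a multi-transcript one either. The actin 3' minus 5' difference lay between 0.89 and 1.83 in fetal and between 2.52 and 4.54 in adult lung arrays. Imprinted growth genes fell in 13 of 17 and rose in 1 (set test adjusted p = 1.6e-09), fetal growth regulators fell in 10 of 11 (set test adjusted p = 1.3e-07), with the same counts adjusted over the list alone, and mitotic genes fell in 29 of 32 (29 adjusted over the list alone; adjusted p = 6.0e-15, and adjusted p = 0.12 with an estimated correlation). Fibrillar collagen and elastic fibre genes fell in 11 of 25 and rose in 3 (the same adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation), the proteoglycan VCAN falling by 1.74 ± 0.23. Macrophage genes rose in 18 of 19 (18 adjusted over the list alone; adjusted p = 3.4e-11, and adjusted p = 0.056 with an estimated correlation, or adjusted p = 0.018 with arrays 10A, 14A and 14B alone), TYROBP by 2.70 ± 0.18. Alveolar type II and surfactant genes rose in 9 of 16 (9 adjusted over the list alone; set test adjusted p = 0.00052). The largest rises were UCP3 (6.23 ± 0.25), PON1 (6.16 ± 0.40), LPO (6.00 ± 0.22), CCL3 (5.92), SPINK1 (5.71) and SAA3 (5.44). NUDT11 fell by 4.91, COL2A1 fell by 4.88, ALAS2 fell by 4.49, ARG1 fell by 4.42 and CATHL1 fell by 4.39. With arrays 10A, 14A and 14B alone ALAS2 fell by 3.26, ARG1 fell by 1.94, CATHL1 fell by 3.29, NUDT11 fell by 5.42 and COL2A1 fell by 5.48.

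Genes that fell with age in both tissues were more than independent lists would share. From fetal day 90 to adulthood 876 genes fell in both tissues against 343 expected of independent lists, a ratio of 2.55, and 833 rose in both against 450, a ratio of 1.85. With lung arrays 10A, 14A and 14B alone these counts were 1075 against 411 expected and 957 against 470 expected. Among the largest shared falls, given as kidney and lung changes, were COL2A1 (-3.98 and -4.88, or -5.48 in lung with those arrays), MDK (-3.93 and -3.76), IGF2BP3 (-3.57 and -3.73), the nucleotide hydrolase NUDT10 (-3.68 and -3.38), IGF2 (-3.22 and -4.19, or 0.29 and -0.01 without multi-transcript probe sets) and UPK1A (-3.93 and -3.21, or -3.90). Others were HBB (-8.04 and -3.32, or -1.03 and -1.83 without those probe sets) and AFP (-6.67 and -4.28, or -2.24 in lung without arrays 26B and 80B), whose lung change was -0.51 (adjusted p = 0.137) without multi-transcript probe sets. The largest shared rises were CCL26 (4.22 and 4.98), AKR1C4 (4.15 and 3.83, or 5.06 in lung with arrays 10A, 14A and 14B alone), FGL2 (5.46 and 3.64), IGHM (3.24 and 4.85), ACSM1 (4.74 and 3.24), ITGAD (3.21 and 3.66), PIGR (3.18 and 4.56) and CYP2B6 (2.80 and 5.08). From fetal day 90 to 10 weeks 738 fell in both (294 expected, ratio 2.51) and 664 rose in both (340 expected, ratio 1.96). With fetal lung arrays 10A, 14A and 14B alone 975 fell and 786 rose in both (392 and 376 expected). Fewer genes changed in opposite directions: 152 rose in kidney and fell in lung and 215 did the reverse between fetal day 90 and adulthood. These stand beside the 876 and 833 that changed in the same direction, and were not set against independent lists. Across genes, which are not independent replicates, the changes of kidney and lung from fetal day 90 to adulthood correlated at r = 0.358.

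Between 10 weeks and adulthood 15 genes fell in both tissues, against 1.68 expected, a ratio of 8.91. They were named after their values were seen: COL1A1 (-1.01 in kidney and -1.04 in lung), COL1A2 (-0.78 and -0.57), COL3A1 (-1.21 and -0.60), the basement membrane genes COL4A1 (-0.57 and -0.70) and NID1 (-0.90 and -0.69), ELN (-0.85 and -1.58), SPARC (-0.88 and -0.83), COLGALT2, GPX7, NREP, PRSS23, EFNB3, MPDZ, IGF2BP3 (-0.98 and -1.71) and MEST (-1.58 and -0.97). At 10 weeks and in adults a MEST probe set nearly as bright as the one used read 8.80 and 8.91 in kidney, and 9.54 and 9.44 in lung. The 4 genes that rose in both tissues stood against 2.90 expected, a ratio of 1.38: the stress factor ATF3, the cysteine dioxygenase CDO1, PRXL2B and LOC524810, a locus identifier. Without fetal lung arrays 26B and 80B these counts were 33 against 6.65 expected (ratio 4.97) and 23 against 9.64 expected (ratio 2.39). The rising count was 2 with the mean of all probe sets, against 2.52 expected. It was 7 without numbers present in both tissues, against 1.87 expected. It also moved to 2 without kidney arrays 7 or 9 at 10 weeks or adult kidney array AD-441, to 7 without adult kidney array AD-444 or adult lung array AD-297, and to 8 without kidney array 11 at 10 weeks. ANKRD1 rose in kidney and fell in lung, and AQP3 and SLC44A4 did the reverse.

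**Figure D4:**
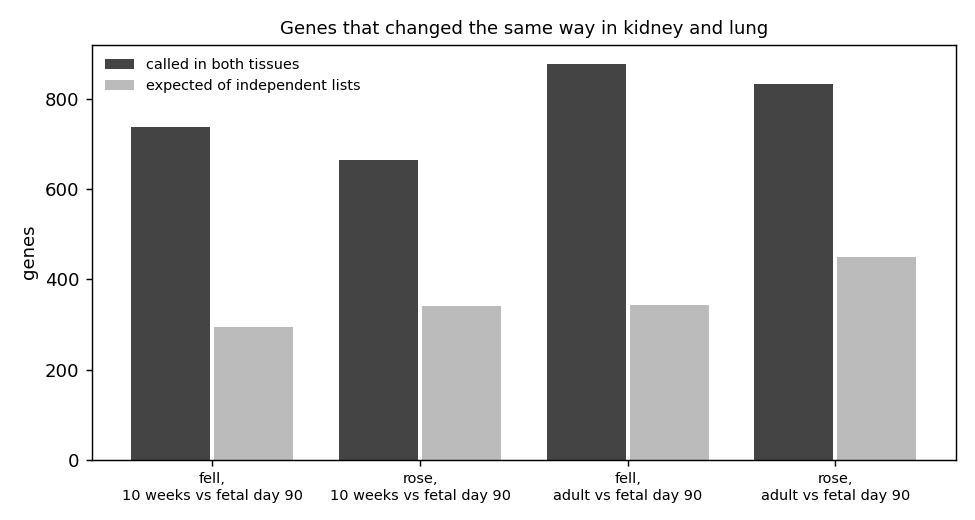
Number of genes (vertical axis, from 0) called in the same direction in kidney and lung (dark bars) and the number expected of independent lists of the same sizes (light bars), by direction and age comparison (horizontal axis). Falls from fetal day 90 to adulthood numbered 876 against 343 expected.

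The change with age differed between the tissues for many genes, tested as an interaction in 1 model of all 30 arrays (lung change minus kidney change). From 10 weeks to adulthood DLK1 fell by 3.61 in lung and changed by -0.20 in kidney, a difference of -3.42 ± 0.35 (adjusted p = 5.36e-07). Adult DLK1 levels were 12.1 ± 0.34 (SD, n = 5) in kidney and 6.30 ± 0.49 in lung. From 10 weeks to adulthood a dimmer DLK1 probe set fell less in lung, from 7.60 to 5.83, and went from 10.08 to 9.81 in kidney. MYBPC1 (-2.78), NUDT11 (-2.60) and ADH4 (-2.34) also differed toward kidney, and BOLA-DQB1 (3.45 ± 0.90, adjusted p = 0.0393), HBB (3.05), CCN5 (2.47) and ADAMTS4 (2.41) toward lung. Leaving out multi-transcript probe sets, the differences were 0.53 for BOLA-DQB1 (adjusted p = 0.204) and 0.01 for HBB (adjusted p = 0.994). With its brightest probe set BOLA-DQB1 read 6.47 to 7.40 in kidney at 10 weeks and 7.08 to 11.61 in adult kidney. Of the imprinted growth genes 4 of 17 differed toward a larger fall in lung and 0 the other way (4 and 0 adjusted over the list alone; adjusted p = 0.0020, and adjusted p = 0.13 with an estimated correlation). Altogether 199 genes differed between tissues at this interval, 137 with the higher change in lung, and 606 without arrays 26B and 80B or 511 with array quality weights. The self-test of an interaction recovered 64.2% of genes given a difference of 1 in the fetal-to-adult interval.

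From fetal day 90 to adulthood 2659 genes had different changes in the 2 tissues, 1526 toward lung and 1133 toward kidney, and from fetal day 90 to 10 weeks 2498 did. Proximal tubule genes differed toward kidney in 15 of 20 and toward lung in 3 (the same adjusted over the list alone; set test adjusted p = 2.7e-07) and fatty acid oxidation genes toward kidney in 15 of 22 (15 adjusted over the list alone; adjusted p = 4.7e-10, and adjusted p = 0.052 with an estimated correlation, or adjusted p = 0.0074 with arrays 10A, 14A and 14B alone). Macrophage genes differed toward lung in 15 of 19 and toward kidney in 1 (16 and 1 adjusted over the list alone; set test adjusted p = 4.7e-10), and fibrillar collagen and elastic fibre genes toward lung in 16 of 25 and toward kidney in 0 (17 and 0 adjusted over the list alone; adjusted p = 1.4e-07, and adjusted p = 0.13 with an estimated correlation, or adjusted p = 0.023 with arrays 10A, 14A and 14B alone). The mitotic genes did not differ as a set (adjusted p = 0.15), with 8 of 32 differing toward lung (8 adjusted over the list alone), and with arrays 10A, 14A and 14B alone adjusted p = 0.0050, 0.43 with an estimated correlation. Single genes with the largest differences in the fetal-to-adult interval were SPINK1 (6.97 ± 0.76), CRABP1 (6.50), UCP3 (6.28) and PON1 (5.92) toward lung, and HRG (-9.41 ± 1.18), TTR (-7.15), LECT2 (-6.92) and SERPINA1 (-6.29) toward kidney. In the fetal-to-10-week interval they were SPINK1 (6.03), FAP (5.56), HTRA4 (5.44) and FST (5.28), and HRG (-8.64), SERPINA1 (-7.31), APOA2 (-7.06) and TTR (-6.99). The last-named plasma protein genes are made in liver and were high in fetal lung arrays 26B and 80B. Without those arrays the fetal-to-adult differences were HRG -7.06, TTR -5.53, LECT2 -4.73 and SERPINA1 -5.23. Those to 10 weeks were HRG -6.29, SERPINA1 -6.24, APOA2 -5.19 and TTR -5.37, and FST was 6.72.

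Lung and kidney themselves differed in 2264 genes at fetal day 90, 4585 at 10 weeks and 4853 in adults. HOXD10 and HOXA10, posterior patterning genes, were lower in fetal lung (-7.84 ± 0.20 and -7.60 ± 0.37), as were the sodium pump subunit FXYD2 (-7.76) and the oxidase HAO2 (-6.72). SFTPC was higher in lung at all ages, by 5.32 ± 0.28 in the fetus, 6.66 at 10 weeks and 6.90 in adults. In fetal lung MEOX2 (5.0), PCOLCE2 (4.54) and ITIH2 (4.46) followed, and ITIH2, a liver protein, was 2.07 higher without arrays 26B and 80B. At 10 weeks and in adults the serine protease HTRA4 (8.08 and 7.80) and CXCL17 (6.56 and 6.94) led, together with TPPP3 (5.38) at 10 weeks and PON1 (6.69) in adults. BBOX1 (-8.79 and -8.13), HAO2 (-8.56 and -8.41) and the tight junction gene CLDN2 (-8.29 and -8.20) were lower in lung at both ages, HOXA10 (-7.85) at 10 weeks and FXYD2 (-7.84) in adults. Among adult differences 2689 genes were higher and 2164 lower in lung, a split that became 2202 higher and 2715 lower when each array was centred on its median. The fetal count was 2737 without arrays 26B and 80B and 4319 with array quality weights.

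To ask how far each tissue had come by 10 weeks, genes were chosen by their fall in the other tissue. In kidney, over the 1555 genes that fell from fetal day 90 to adulthood in lung, the mean went from 9.0 ± 0.03 (SD, n = 5) in the fetus to 8.54 ± 0.04 at 10 weeks and 8.48 ± 0.03 in adults, so that 88.3% of the fall was present at 10 weeks (95% bootstrap interval over arrays 79.8 to 95.9). In lung, over the 2019 genes that fell in kidney, the mean went from 9.03 ± 0.13 to 8.74 ± 0.03 and 8.68 ± 0.05, a share of 83.0% (69.3 to 94.8), and 86.1% with arrays 10A, 14A and 14B alone. The intervals overlap. For the imprinted growth genes the share was 79.6% in kidney (73.7 to 85.7) and 60.2% in lung (54.8 to 66.2). For the fetal growth regulators it was 79.0% (74.0 to 83.7) in kidney and 65.9% (56.0 to 76.1) in lung, and for the mitotic genes 71.6% (62.7 to 80.4) and 85.5% (74.4 to 98.8). DLK1 is in both growth lists, so their shares are not separate observations. Its lung means went from 12.6 to 9.92 to 6.30, and the shares without it were not computed. The difference of these shares between tissues was not tested. Fibrillar collagen and elastic fibre genes had a share of 78.3% in kidney, but in lung the interval from -298 to 529 gave no share, and with 3 fetal arrays it was 38.5% (28.7 to 51.4).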

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

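The tests of RNA integrity, of absent lung RNA and of DQ differences between animals were chosen only after the result was seen, and the other tests in this part were written before the values they measure were seen, although the list of further hepatocyte genes and the leaving out of 26B and 80B, on which 2 of them rest, were themselves chosen after the data were seen.

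In the fetal lung, array 26B had a mean correlation of 0.918 with the other arrays of its group, far from them, and the median of array 80B (6.69) lay below the others. In this group 9 of 35 gene lists had an array far from the others, in each case 26B, and 18 of 83 named genes did, 16 of them in 26B. About 5% would by chance. Fibrillar collagen and elastic fibre genes averaged 9.42 in 26B and 10.4 over the other 4, and macrophage and monocyte genes 7.86 and 6.92. Other single arrays lay apart as well: adult kidney AD-444 by its mean correlation (0.984) and adult lung AD-287 by its actin 3' minus 5' difference (4.54). Over the liver transcripts adult lung AD-204 had a mean of 6.76, against 5.12 to 5.39 in the other adult lung arrays. Lists with an array apart numbered 1 in adult kidney, 5 in kidney at 10 weeks, 1 in adult lung and 4 in lung at 10 weeks, and named genes 7 in adult kidney, 3 in fetal kidney, 5 in kidney at 10 weeks, 10 in adult lung and 6 in lung at 10 weeks. With 30 array measures, 35 lists and 83 genes per group, several of these would arise by chance.

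RNA from liver may account for why 26B and 80B stood apart. Over 32 further hepatocyte genes, not looked at before the test, the median excess over the other 3 arrays was 4.37 in 26B and 1.60 in 80B, with 26 and 22 of the 32 over 1 log2, although 6 of the 32 were also high in fetal kidney. Lower RNA integrity in both arrays is argued against, since the lower actin 3' minus 5' difference of the 2 arrays lay at -0.94 relative to the highest of the other 3. By the GAPD 3' minus 5' difference 26B (-0.64) was the lowest of the group and 80B (-0.07) the highest, so 80B alone is not settled. That array 26B is a liver sample with a lung label, with no lung RNA, is argued against: over the 8 lung genes at least 2 log2 above fetal kidney in the other 3 arrays, its median excess over fetal kidney was 1.41, and 8 of 8 lay above every kidney array, SFTPC at 9.30 against 5.12 to 6.35 in fetal kidney. Earlier tests decided nothing and were replaced after their results were seen: a median over 16 alveolar type II genes read 0.407 in 26B and between 0.381 and 0.528 in the other 4, and one over 17 lung genes 0.993. HOXA10, lower in fetal lung than in fetal kidney, also read 6.75 in 26B against 3.59 over the other 4. On the first principal component 26B lay at 1.18, the other 4 between -30.7 and -19.4 and fetal kidney between 22.2 and 23.0. Whether liver RNA accounts for these values was not tested. How the liver transcripts came into these arrays stays open, no liver array was there for comparison, and no biological explanation was tested.

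Genes that fell in both tissues from fetal day 90 to adulthood could reflect animals shared by both tissues or the liver RNA of the 2 fetal lung arrays, rather than a common change. With no number in both tissues the ratio to independent lists was 2.93, and with arrays 10A, 14A and 14B alone it was 2.62, so both are argued against as the whole cause. Age itself, which all animals of a group share, stays open and untested against other causes, such as a change in the mix of cells common to both organs.

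BOLA-DQA1 and BOLA-DQB1 rose in lung from 10 weeks to adulthood by a mean of 5.19, though BOLA-DQB1 by 0.30 (adjusted p = 0.264) without probe sets named as matching several transcripts. In lung BOLA-DQB1 read 7.30 to 9.88 in the fetus, 5.75 to 6.38 at 10 weeks and 9.59 to 12.67 in adults. In kidney it read 9.36 to 10.01, 6.47 to 7.40 and 7.08 to 11.61, with AD-432 and AD-434 at 7.18 and 7.08. The BOLA-DQB1 rise thus started from a 10-week level below the fetal one. For BOLA-DQA1 fetal and 10-week lung arrays overlapped (5.32 to 8.67 and 5.37 to 6.61). A change in cells that carry MHC class II is argued against: the median rise of 5 other class II genes was 0.00018, or 0.00347% of the DQ rise. Differences between animals in how DQ transcripts meet the bovine probes may explain it and stay open. BOLA-DQA1 deviations of same-numbered lung and kidney arrays differed by 0.185 on average against a median of 0.771 over 144 re-pairings of 7 pairs (exact one-sided permutation p = 0.0556), a p that neither passes the threshold nor shows that DQ levels were unrelated. Fetal number 80B read 8.80 in kidney and 8.67 in lung, against 5.32 to 7.15 in the other fetal arrays. No adult number was in both tissues and pairing was not established, so the test cannot decide about the adult arrays. The adult animals differ from those at 10 weeks, so age stays open as well.

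Changes that differed between lung and kidney were tested as interactions. From fetal day 90 to 10 weeks 2498 genes and 16 lists differed, the largest being SPINK1 (6.03), FAP (5.56), HTRA4 (5.44), FST (5.28), HRG (-8.64), SERPINA1 (-7.31), APOA2 (-7.06) and TTR (-6.99). From 10 weeks to adulthood 199 genes and 3 lists differed, the largest being BOLA-DQB1 (3.45), HBB (3.05), CCN5 (2.47), ADAMTS4 (2.41), DLK1 (-3.42), MYBPC1 (-2.78), NUDT11 (-2.60) and ADH4 (-2.34). Without multi-transcript probe sets the calls of BOLA-DQB1 (0.53, adjusted p = 0.204) and HBB (0.01, adjusted p = 0.994) were lost. From fetal day 90 to adulthood 2659 genes and 14 lists differed, the largest being SPINK1 (6.97), CRABP1 (6.50), UCP3 (6.28), PON1 (5.92), HRG (-9.41), TTR (-7.15), LECT2 (-6.92) and SERPINA1 (-6.29). The liver transcripts among these were high in 26B and 80B.

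Of 10638 probe sets not listed with a gene, controls left out, the number that differed was 3254 for kidney from fetal day 90 to 10 weeks, 198 from 10 weeks to adulthood and 3380 from fetal day 90 to adulthood, and 2031, 167 and 2944 for lung. They have no gene name here.

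Of 100 splits of the arrays, only the real one gave as large a count of genes called, in each age and tissue comparison. For each interaction only the real data did so among 100 counts, the others coming from shuffled residuals of a fit without interaction. Causes that run along with age or tissue, such as RNA quality, were not addressed by this. A true difference also enters the spread of the other splits, and of the shuffled residuals, and lowers their counts. The highest of the others, beside the real count, was 1 beside 4111, 69 beside 300 and 1160 beside 4198 for kidney, and 1099 beside 2820, 1 beside 289 and 1241 beside 3444 for lung, in the order fetal to 10 weeks, 10 weeks to adult and fetal to adult. It was 12 beside 2498, 2 beside 199 and 16 beside 2659 for the interactions, and 1579 beside 2264, 2497 beside 4585 and 2495 beside 4853 between tissues at fetal day 90, 10 weeks and adulthood. For genes shared by both tissues it was 0 beside each of 738, 664, 15, 4, 876 and 833. However, 0 of the 99 other splits called genes in the same direction in both tissues, so these splits decide nothing about overlap. The 4 shared rises from 10 weeks to adulthood stood beside 2.90 expected of independent lists. That comparison depended on the setting: 23 stood beside 9.64 expected with fetal lung arrays 10A, 14A and 14B alone. With no number in both tissues 7 stood beside 1.87 expected, and with the mean of all probe sets 2 stood beside 2.52. Summed over the 6 age comparisons, 87 list calls stood beside 71. Within a single comparison the number of lists called was matched by 5, 1 and 13 of 100 splits in kidney. In lung it was matched by 14, 21 and 16, the real one included in each case. Only in kidney from 10 weeks to adulthood did no other split call as many lists.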

How the results depend on the processing

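Leaving out fetal lung arrays 26B and 80B was chosen only after the result was seen. The other alternatives were set earlier. The cause of each change below was not tested unless stated.

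Requiring at least 2-fold as well, which by construction calls fewer genes, left 955, 59 and 1008 genes in kidney (fetal to 10 weeks, 10 weeks to adult, fetal to adult), 908, 87 and 1192 in lung. It left 1209, 97 and 1318 in the interactions and 696, 1730 and 1795 between tissues at the 3 ages. At least 2-fold in both tissues, 164 fell and 136 rose to 10 weeks, 1 fell and 0 rose from 10 weeks to adulthood, and 208 fell and 163 rose from fetal day 90 to adulthood.

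The kidney count from 10 weeks to adulthood was 137 with all 30 arrays in the fit and 158 with only the 10 arrays compared. With array quality weights the counts were 4824 for lung from fetal day 90 to 10 weeks, 1204 for lung from 10 weeks to adulthood, 511 for the interaction at that interval and 4319 between tissues at fetal day 90. For lung from 10 weeks to adulthood the count was 751 with all 30 arrays, 689 with only 10 and 1020 without 26B and 80B. Without these 2 arrays the interaction at that interval called 606, and 33 genes fell and 23 rose in both tissues, against 6.65 and 9.64 expected. Those that rose in both numbered 2 with the mean of all probe sets and 7 with no number in both tissues, against 2.52 and 1.87 expected.

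The replicate block, taking a number in the titles as an animal within an age, gave 332 genes for the interaction from 10 weeks to adulthood, with a consensus correlation of 0.218. Over 7 shared numbers r lay between 0.0761 and 0.25 and was over 0.1 in 6. As pairing was to be accepted only with each of the 7 over 0.1, it was not established, and 3 of 7 kidney arrays were closest to their own number.

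The kidney share of the fall was 95.8% with arrays centred on their medians, 79.3% with the fixed growth lists and 71.6% with the mitotic list, and the lung share was 65.3% with the growth lists. The lists called in the age comparisons fell from 87 to 43 with an estimated correlation, and numbered 91 without 26B and 80B.

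Directions that reversed all depended on the probe set. Without the probe sets whose names mark a match to several transcripts, of one gene or of different genes, IGF2 changed by 0.32 in kidney from fetal day 90 to 10 weeks and by 0.29 to adulthood, by 0.22 in lung from fetal day 90 to 10 weeks, and HBB by -0.26 in lung from 10 weeks to adulthood. The IGF2 call was lost in lung from 10 weeks to adulthood (-0.23) and from fetal day 90 to adulthood (-0.01). These IGF2 values came from the brightest remaining probe set. A dimmer remaining set fell from fetal day 90 to adulthood, from 7.71 to 6.36 in kidney and from 8.14 to 6.46 in lung. CD2AP in lung from fetal day 90 to adulthood changed by -0.20 with the mean of all probe sets and by -0.70 without those probe sets. Over named genes and the alternatives set earlier other than leaving out an array, 6163 results kept direction and side of the threshold, 98 lost the call, 6 gained it and 6 reversed. Without 26B and 80B 367 kept both, 5 lost the call and 2 gained it. For lists 205 kept and 56 lost the call.

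Leaving out each array in turn, the counts ranged over 3736 to 4016, 222 to 308 and 3833 to 4273 in kidney, 2384 to 3473, 165 to 273 and 3009 to 4088 in lung. They ranged over 2332 to 2656, 133 to 238 and 2444 to 2915 in the interactions, and 1935 to 2758, 4328 to 4476 and 4518 to 4731 between tissues. Genes that fell in both ranged over 617 to 990, 10 to 15 and 754 to 1083, and those that rose in both over 587 to 814, 2 to 8 and 749 to 1003. The shares ranged from 86.2% to 92.2% in kidney and from 79.9% to 86.4% in lung. Of named gene results 7143 kept direction and side, 234 lost the call, 3 gained it and 0 reversed. Signal over background was not available, so what dim probe sets limit is unknown.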

Other observations

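The values in this part are descriptive, and no explanation was tested here. Gene lists with little or no description above are given first, for the 6 age comparisons in the order kidney and then lung, each from fetal day 90 to 10 weeks, from 10 weeks to adulthood and from fetal day 90 to adulthood, with the set test adjusted p.

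Genes of the IGF axis gave 0.72, 0.072 and 0.84 in kidney and 0.22, 0.11 and 0.098 in lung. The mean of that list went from 8.83 to 8.36 to 8.22 in lung. In kidney from fetal day 90 to 10 weeks IGFBP3 rose by 0.96 and IGFBP4 by 0.95, while IGF2R fell by 0.34. Cell cycle inhibitors gave 0.76, 0.024 and 0.28, and 0.37, 0.95 and 0.51. Collagen processing enzymes gave 0.021, 0.00073 and 0.0014 in kidney, where 6, 2 and 8 of 13 fell, but 0.17, 0.083 and 0.082 with an estimated correlation, and 0.17, 0.95 and 0.20 in lung. Lung bud and lung development genes gave 0.29, 0.79 and 0.36, and 0.23, 0.46 and 0.20. Podocyte and glomerulus genes gave 0.72, 0.12 and 0.95, and 0.0025, 0.11 and 0.096.

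Complement and acute phase genes gave 0.0093, 0.72 and 0.045 in kidney, with 0.13 to 10 weeks and 0.22 from fetal day 90 to adulthood at an estimated correlation, and 0.064, 0.19 and 0.026 in lung. Granulocyte and mast cell genes gave 0.36, 0.67 and 0.27, and 0.97, 0.93 and 0.93. Adipocyte genes gave 0.075, 0.15 and 0.30, and 0.082, 0.95 and 0.096. Smooth and skeletal muscle genes gave 0.93, 0.79 and 0.73, and 0.088, 0.69 and 0.096. Adrenal and steroid synthesis genes gave 0.18, 0.67 and 0.15, and 0.044, 0.95 and 0.096. Nerve and glia genes gave 0.031, 0.072 and 0.31, and 0.031, 0.93 and 0.096. Cytosolic ribosomal protein genes gave 0.35, 0.67 and 0.46, and 0.018, 0.028 and 0.54. Of 2 sex-linked transcripts measured, too few for a set test, 0 were called in kidney and 1 fell in lung from fetal day 90 to 10 weeks and 1 from fetal day 90 to adulthood.

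The other calls among these lists were lost with an estimated correlation: cell cycle inhibitors in kidney from 10 weeks to adulthood (adjusted p = 0.15), podocyte and glomerulus genes in lung to 10 weeks (0.12), complement and acute phase genes in lung from fetal day 90 to adulthood (0.58), adrenal and steroid synthesis genes in lung to 10 weeks (0.30), nerve and glia genes to 10 weeks in kidney (0.10) and lung (0.083), and ribosomal protein genes in lung to 10 weeks (0.62) and from 10 weeks to adulthood (0.98).

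Lists described above for some intervals only were called at others too. In kidney from 10 weeks to adulthood 2 of 16 chromatin and DNA methylation genes fell (adjusted p = 0.017, and 0.062 with an estimated correlation) and 2 of 21 immediate early and heat shock genes rose (0.043, and 0.28). Between fetal day 90 and adult kidney 22 of 30 xenobiotic and antioxidant genes rose and 1 fell (2.5e-08), 8 of 16 distal nephron genes rose (0.0018), 9 of 13 MHC class II genes rose and 1 fell (0.0044), and 18 of 41 oxidative phosphorylation genes rose (0.00055, and 0.42). Lower there were 11 of 16 chromatin genes (7.3e-06) and 6 of 11 nephron progenitor genes, with 2 higher (0.029, and 0.12).

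In lung to 10 weeks 15 of 30 xenobiotic and antioxidant genes rose and 1 fell (1.3e-06), and 5 of 41 oxidative phosphorylation genes fell (0.031, and 0.62). After 10 weeks 2 of 12 airway genes rose (0.0091, and 0.56). Over the whole span from fetal day 90 to adult lung the lists that were higher were xenobiotic and antioxidant genes (21 of 30 rose, 2 fell, 5.2e-07), T and NK cells (14 of 19 rose, 1 fell, 1.9e-06), B and plasma cells (9 of 11, 5.7e-06) and MHC class II (9 of 13, 1.9e-06). Others were called at the preset correlation alone: alveolar type I (12 of 14 rose, 1 fell, 7.3e-06, and 0.058), airway (9 of 12, 7.3e-06, and 0.059), interferon response (14 of 19 rose, 1 fell, 1.8e-05, and 0.058), endothelium (9 of 19, 0.010, and 0.39) and immediate early genes (17 of 21 rose, 1 fell, 9.9e-09, and 0.056). Chromatin genes fell in 10 of 16 (7.3e-06) and erythroid genes in 5 of 17 (0.0049, and 0.46). A list was not called with all arrays at an age interval for which no value is given.

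With fetal lung arrays 10A, 14A and 14B alone, chosen after the data were seen, further lists were called in lung at the preset correlation. Those to 10 weeks were complement and acute phase genes (adjusted p = 6.9e-06, and 0.065 with an estimated correlation), adipocyte genes (0.019, and 0.065) and collagen processing enzymes (0.024, and 0.19), while the calls of erythroid (0.30) and oxidative phosphorylation genes (0.30) were lost. Between fetal day 90 and adulthood adipocyte genes (0.025, and 0.059) and collagen processing enzymes (0.044, and 0.21) were gained, and erythroid (0.20) and endothelial genes (0.076) lost. From 10 weeks to adulthood complement and acute phase genes (0.0012, and 0.29), oxidative phosphorylation genes (0.032, and 0.45), xenobiotic and antioxidant enzymes (0.030, and 0.45) and endothelial genes (0.045, and 0.45) were gained, and ribosomal protein genes (0.080) lost.

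BOLA-DQA1 varied widely between adult kidney arrays, with a mean of 7.80 and an SD of 2.57.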
